A study of Danio rerio with 3 samples.

How the data were processed

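Whole zebrafish embryos of strain AB were injected with a morpholino (MO), an antisense oligomer that blocks splicing or translation of its target. The slc2a10 MO covers the splice donor site of exon 2 of slc2a10, the gene of the glucose transporter family member GLUT10, and was given at 7.5 ng per embryo, while a control MO was given at 5 ng, per the labels. Embryos were collected at 48 hours post fertilization, and the embryos given slc2a10 MO had been sorted for a recognizable (Class 1) phenotype. Each of 3 biological replicates held the RNA of 10 to 15 embryos. The RNA of control embryos was pooled into 1 control sample before linear T7 amplification and labelling with ULS Cy3 or Cy5, per the labels' protocols. Each slc2a10 MO replicate was hybridised together with this pool on 1 of 3 two-colour Agilent zebrafish arrays. The slc2a10 MO sample was in Cy3 on replicates 1 and 3 and in Cy5 on replicate 2.

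The deposited values are 1 log ratio per probe and array, made by the authors and read here as log2 ratios. The largest had a size of 4.85, which as a log10 ratio would exceed the range of a 16-bit scanner. A natural log was not excluded, and all log2 sizes would then be understated. Partek is named in the submitters' processing notes with no version or role. The scanner, the background correction, the normalization within arrays and the direction of the ratio are not given in the sources used here. Scanner files were not analysed here, so signal above background, saturation and spot flags are unknown for every probe. The deposited columns had medians of -0.0016, -0.0075 and -0.0045, so the arrays had been centred before deposit. No value was missing, and the number of arrays limits the precision.

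The values of replicate 2 correlated over all probes at -0.65 with replicate 1 and at -0.69 with replicate 3, while replicates 1 and 3 correlated at 0.48. By a rule fixed before the data were examined, the ratios were therefore taken as running by dye, and the sign of replicate 2 was turned. Ratios that the submitters had already turned by sample, with a dye bias larger than the difference between samples, would give correlations of the same signs, and the deposited values do not exclude this. The turn puts the 3 arrays in 1 direction but does not say which direction that is. The labels list Cy5 as the first channel, and Agilent's own log ratio is Cy5 over Cy3, but the sample titles name the Cy3 sample first. The direction of the whole table was therefore left open. All values are given relative to slc2a10 itself, with positive values on the slc2a10 side and negative values on the opposite side. If the deposited ratios are Cy5 over Cy3, the slc2a10 side was higher in the control pool. If they are Cy3 over Cy5, it was higher in the knockdown embryos.

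Of 43648 measured features, 45 control spots were left out and 43603 probes were tested. Gene names came from GEO's annotation of the platform, updated through Entrez IDs for 23534 probes and through accessions for 42 with the RefSeq gene table of the GRCz12tu assembly, which changed the symbol of 21. The earlier symbol was kept for 141 probes. In all, 23717 probes had 1 gene symbol, none had several, and 19886 were unnamed here. Probes of a gene were averaged per array, giving 15548 named genes, of which 6107 had more than 1 probe.

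Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as the mean log2 ratio of the 3 arrays against 0, without a dye term, at a Benjamini-Hochberg adjusted p under 0.05. The control pool is 1 control sample present on all arrays. The test leaves out the spread between control embryos, and a peculiarity of the pool would appear on every array. With 3 arrays an exact sign test cannot pass 0.05, so the calls rest on limma's pooling of spread across genes. The model treats the 3 arrays as independent. Ratios were simulated for 3 independent arrays of equal spread, using limma's moderated variance of each of the 15548 genes. All 100 genes changed by 0.5 log2 and all 100 changed by 1 log2 were recovered (100% of each). With them, 18 unchanged genes were called, which made up 8.26% of the calls. That setting follows limma's own model. It held 200 changed genes, while 2996 genes were called in the real data and only 297 of these reached 1.5-fold. Recovery of smaller changes was not simulated. In the real data limma weighted the arrays unequally and their independence is in doubt, so these rates need not hold.

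Before the data were examined, 27 gene lists were fixed. They covered metabolism (nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded genes, glycolysis, glucose transporters), signalling and matrix (TGF-beta and BMP pathway components and their transcriptional targets, collagens, elastic fibre genes), stress (oxidative stress, hypoxia, heat shock and unfolded protein response, p53 targets, interferon response) and DNA replication and mitosis. The rest were markers of notochord, cardiac, skeletal and smooth muscle, endothelium, erythroid and myeloid cells, neurons, retina and lens, liver with yolk and gut, pigment cells, epidermis, and cartilage with bone. The lists share some members. They were tested with limma's camera at its preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation and fry stood beside it. Fry tests the members of a list against no change, in 1 direction on balance or in either direction, and compares them with no other genes. With 2 residual degrees of freedom the correlation in camera is poorly estimated. In that form camera also refers its statistic to those 2 degrees of freedom, so hardly any list can pass after adjustment, whatever its correlation. For leukocyte markers the estimated correlation was -0.0057, below the preset, yet camera's unadjusted p rose from 0.00024 to 0.056. Failing that form is therefore, by itself, little evidence that correlated members made a call. The estimate was also below the preset for neurons (0.0080) and mitochondrially encoded genes (-0.15). It was above the preset for retina and lens (0.20), glycolysis (0.12), oxidative phosphorylation (0.10) and pigment cells (0.090). The same held for skeletal muscle (0.046) and DNA replication (0.025). For these lists the preset may have made camera's p too small. Named genes followed a rule fixed at the same time. They are slc2a10, the 12 largest called differences on each side with the same sign on all 3 arrays, leaving out clone and locus placeholders, and up to 4 members of each list with the smallest p.

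The alternatives were the opposite turn of replicate 2, all signs turned, a dye term, median centring, scaling to 1 median absolute deviation, quantile normalization, robust eBayes, array weights, an ordinary t statistic, the median of a gene's probes, a 1.5-fold minimum and leaving out each replicate. Background correction and normalization within arrays could not be varied from the deposited ratios.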

Results

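Transcript levels were compared between zebrafish embryos in which slc2a10 was knocked down and embryos given a control MO, to find which genes differ at 48 hours post fertilization. SLC2A10 encodes GLUT10, a facilitative transporter whose loss in humans causes arterial tortuosity syndrome, a connective tissue disease of the large arteries. The data were log2 ratios from 3 arrays, each holding 1 slc2a10 MO replicate against the same control MO pool. Signs are relative to slc2a10. The slc2a10 side was higher in the control pool if the ratios are Cy5 over Cy3, and higher in knockdown embryos if they are Cy3 over Cy5. Values are means ± SD of the 3 arrays (n = 3). The SD covers the knockdown replicates only. MO dose and the sorting of knockdown embryos by phenotype differed along with the target.

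The knocked-down gene itself differed between the groups. The single slc2a10 probe gave 0.50, 0.42 and 0.47 on replicates 1, 2 and 3, a mean of 0.46 ± 0.04 (1.38-fold, limma adjusted p = 0.0008). An MO at a splice donor site need not change the amount of transcript, and the position of the probe in slc2a10 is not given in the sources used here. Its sign therefore does not check the labels. The glucose transporter list holds slc2a10 itself and also names genes of another family, slc23a1, slc23a2 and slc23a3. Of its 13 measured genes, 2 were called, slc2a10 and slc2a2 (0.34 ± 0.07). Both lay on the slc2a10 side and were also called when adjusted over the list alone. The list did not differ from other genes by camera (adjusted p = 0.24). The values of slc2a15b (0.12 ± 0.07) and slc2a12 (0.06 ± 0.06) did not pass.

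Across the genome, 2996 of 15548 named genes (19.3%) differed, 1728 on the slc2a10 side and 1268 on the opposite side. Most differences were small: 297 genes reached 1.5-fold (202 and 95), and 58 reached 2-fold (44 and 14). Among the unnamed probes, 1178 of 19886 differed, 503 on the slc2a10 side and 675 on the opposite side. Leaving out replicate 2, the only array of its dye order, gave 1556 genes. An ordinary t statistic gave 2, and with the sign of replicate 2 left as deposited limma gave 0 (28 at an unadjusted p under 0.05).

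Among the 12 largest differences on the slc2a10 side, the carboxylesterase gene ces3 came first at 3.63 ± 0.21 (12.3-fold), an average of 2 probes that disagreed in size (4.58 and 2.68). It was followed by the G protein beta subunit gene gnb3a at 2.16 ± 0.19. Col10a1a, encoding the type X collagen of cartilage and bone, stood at 2.14 ± 0.23, and matn1, encoding the cartilage matrix protein matrilin 1, at 1.75 ± 0.21. Other members were the photoreceptor transcription factor crx (1.99 ± 0.59), the bipolar cell transcription factor vsx1 (1.81 ± 0.36) and the retinoid isomerase of the pigment epithelium rpe65a (1.68 ± 0.16). The liver fatty acid binding protein gene fabp10a reached 1.92 ± 0.13 and the histidine-degrading enzyme gene ftcd 1.55 ± 0.21. The remaining 3 of the 12 were the small heat shock protein gene hspb9 (1.89 ± 1.19), comtd1 (1.58 ± 0.04) and fabp4b (1.57 ± 0.16). For hspb9 the arrays ranged from 0.65 to 3.02, and its call was lost with robust eBayes (adjusted p = 0.22).

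Among the 12 largest differences on the opposite side, the cathepsin S gene ctss2.1 lay at -2.60 ± 0.30, ctsh, encoding cathepsin H, at -1.24 ± 0.16, and psap, encoding the precursor of the saposins, at -1.23 ± 0.16. The stress-induced regulator nupr1 followed ctss2.1 at -1.82 ± 0.22. The pyrimidine synthesis enzyme gene cad (-1.44 ± 0.08) averaged 4 probes between -2.17 and -1.52 and 1 near no change (-0.03). Others were afp4 (-1.49 ± 0.48), the complement inhibitor gene serping1 (-1.42 ± 0.16), arrdc2 (-1.39 ± 0.23), the embryonic beta globin gene hbbe3 (-1.31 ± 0.26), cart3 (-1.23 ± 0.14), the histone H1 gene histh1l1 (-1.09 ± 0.14) and the translation repressor gene eif4ebp3l (-1.02 ± 0.06). All 24 genes had the same sign on the 3 arrays, as the rule for naming them required.

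**Figure D1:**
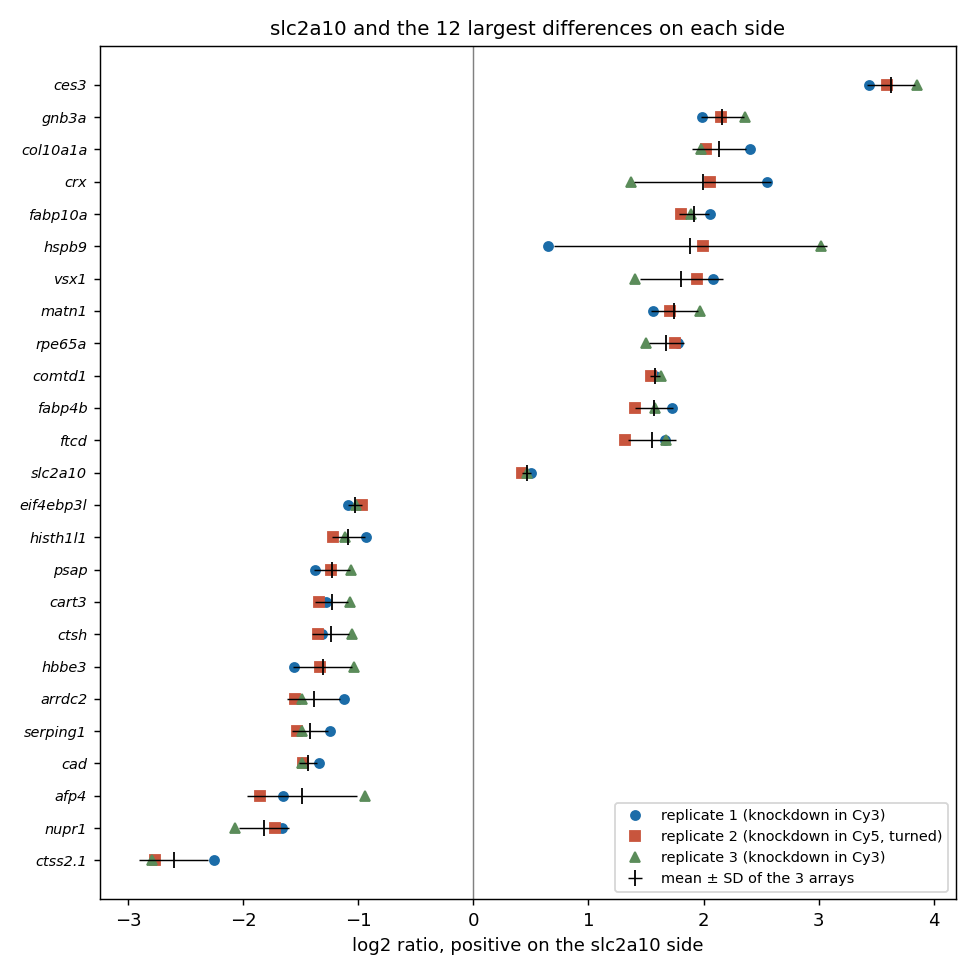
Log2 ratios (x axis, positive on the slc2a10 side) of slc2a10 and of the 12 largest called genes on each side (y axis), with 1 symbol per array and the mean ± SD of the 3 arrays as a black tick and line. The 3 arrays lie close together for most genes, while hspb9 spans 0.65 to 3.02.

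Gene lists fixed before the data were examined were then compared with all other genes. Of 27 lists, 9 differed by camera. None passed with an estimated correlation, where 2 degrees of freedom leave little chance of passing. For several of the 9 lists the estimated correlation was above the preset, so camera's p at the preset may be too small. Fry, which tests a list against no change and not against other genes, called 4 lists in 1 direction and all 27 in either direction. Genes of DNA replication and mitosis lay on the opposite side. Of 50 measured members 40 were called there and 0 on the slc2a10 side (45 and 0 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 7.1e-26, and adjusted p = 0.34 with an estimated correlation). The replicative helicase subunit genes mcm4 and mcm5 had -0.63 ± 0.03 and -0.64 ± 0.10. The thymidylate synthase gene tyms had -0.68 ± 0.13, and the origin licensing gene cdc6 -0.62 ± 0.10. The list medians were -0.38, -0.41 and -0.39 on replicates 1, 2 and 3.

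Genes of mitochondrial respiration lay on the slc2a10 side. Of 83 nuclear-encoded oxidative phosphorylation subunits 60 were called there and 0 on the opposite side (64 and 0 adjusted over the list alone). The median was 0.32 (camera adjusted p = 4.2e-21, and adjusted p = 0.50 with an estimated correlation). Examples were cyc1 (0.75 ± 0.11) and uqcrb (0.54 ± 0.10) of complex III, cytochrome c itself (cycsb, 0.62 ± 0.13) and cox5aa of complex IV (0.51 ± 0.07). Of 6 mitochondrially encoded genes 3 were called on the slc2a10 side, also when adjusted over the list alone: ND1 (0.33 ± 0.06), ND3 (0.33 ± 0.12) and ND5 (0.26 ± 0.15). All 6 were above 0 (camera adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation). Of 40 glycolysis genes 14 were called on the slc2a10 side and 4 on the opposite side, the same counts as adjusted over the list alone (camera adjusted p = 0.0051, and adjusted p = 0.62 with an estimated correlation). Eno2 (0.56 ± 0.10), pkmb (0.67 ± 0.20) and pgam1b (0.48 ± 0.08) lay on the slc2a10 side, while the phosphofructokinase gene pfkmb lay at -0.61 ± 0.17.

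Several sets of tissue markers lay on the slc2a10 side. Of 58 retina and lens genes 21 were called there and 1 opposite (22 and 2 adjusted over the list alone), with rpe65a and vsx1 joined by the arrestin gene sagb (2.29-fold, with an SD of 0.06 in log2) and the retinoid-binding protein gene rlbp1b (0.80 ± 0.02). Camera gave an adjusted p of 3.0e-05, and an adjusted p = 0.62 with an estimated correlation. Of 50 skeletal muscle markers 21 were called on the slc2a10 side and 8 opposite (25 and 9 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.60 with an estimated correlation). The muscle glycogen phosphorylase gene pygma was on the opposite side (-0.76 ± 0.10), and myoz1a (0.80 ± 0.14), pvalb1 (0.58 ± 0.06) and acta1b (0.57 ± 0.08) were on the slc2a10 side. Of 27 neural crest and pigment cell genes 8 were called, all on the slc2a10 side (9 and 0 adjusted over the list alone; camera adjusted p = 0.0040, and adjusted p = 0.60 with an estimated correlation). Among them were the melanosome gene pmelb (0.76 ± 0.19), the neural crest regulator gene tfap2a (0.45 ± 0.05), tfap2e (0.48 ± 0.15) and pnp4a (0.36 ± 0.08). Neural genes went both ways. Of 37, 19 were called on the slc2a10 side and 11 opposite (21 and 12 adjusted over the list alone; camera adjusted p = 0.040, and adjusted p = 0.60 with an estimated correlation). The genes neurod1 (1.14 ± 0.04), snap25b (0.88 ± 0.16) and fabp7a (0.83 ± 0.15) were on the slc2a10 side, and the retinal progenitor factor gene atoh7 was opposite (-0.66 ± 0.11).

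Myeloid genes lay on the opposite side. Of 23 leukocyte markers 8 were called there and 0 on the slc2a10 side, the same counts as adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.50 with an estimated correlation). They included the lysozyme gene lyz (-0.70 ± 0.27), the neutrophil peroxidase gene mpx (-0.59 ± 0.22, with 3 of its 4 probes on this side) and the metalloproteinase genes mmp9 (-0.84 ± 0.43) and mmp13a (-0.53 ± 0.26). Of 29 interferon and innate immune genes 2 were called, both on the opposite side (1 adjusted over the list alone): b2m (-0.34 ± 0.10) and socs3a (-0.26 ± 0.14). The list did not pass by camera (adjusted p = 0.15).

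**Figure D2:**
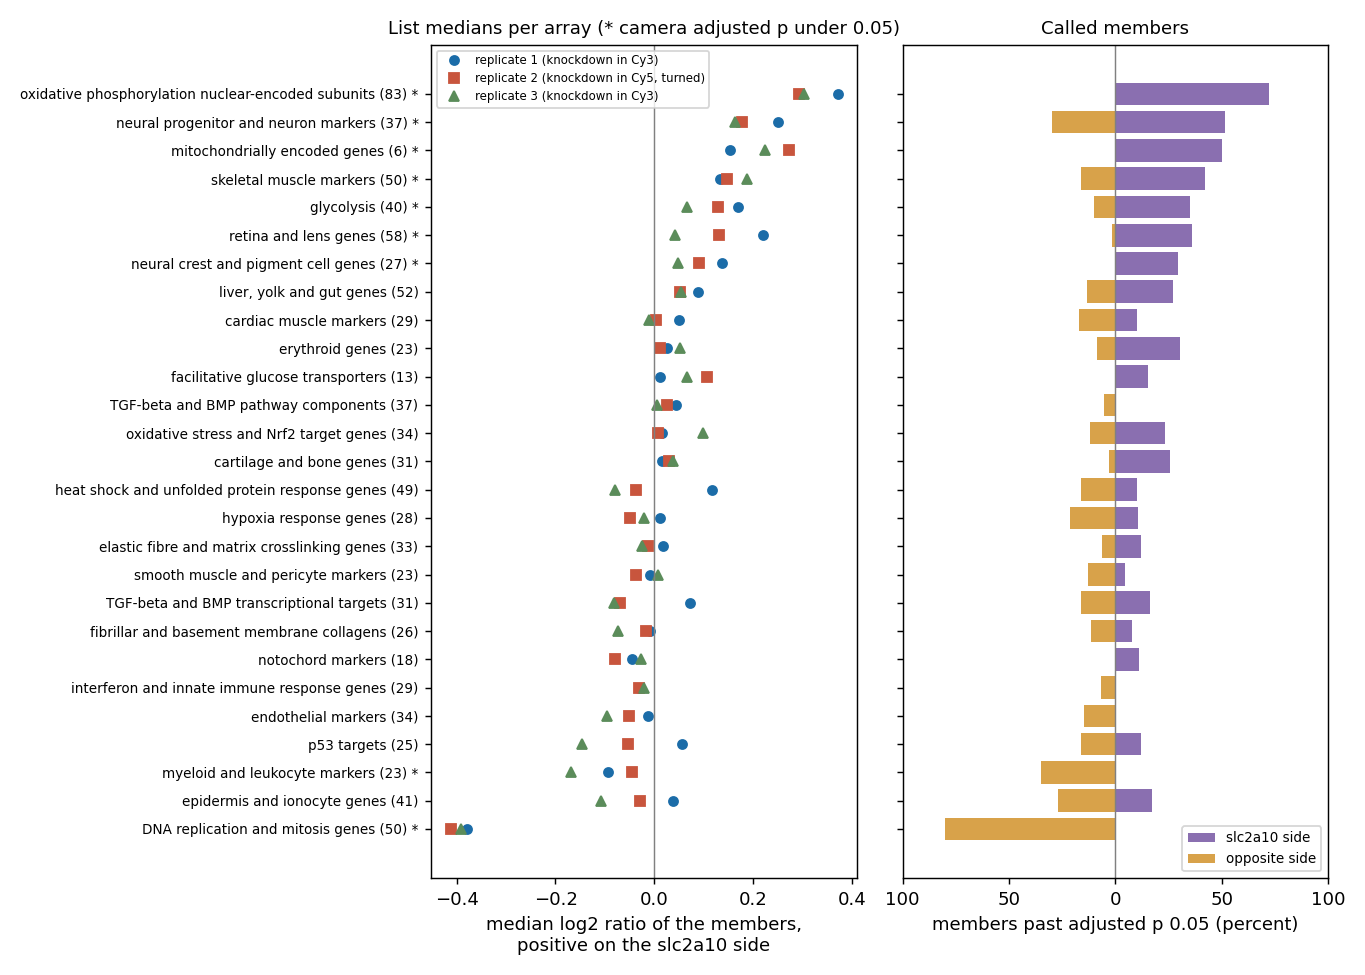
Left, median log2 ratio of the members of each fixed list on each array (x axis, positive on the slc2a10 side), with the number of measured members in brackets and a star where camera's adjusted p was under 0.05. Right, percent of members called on the slc2a10 side (to the right of 0) and on the opposite side (to the left); 40 of 50 replication genes and 60 of 83 oxidative phosphorylation genes were called.

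The lists closest to the vascular and connective tissue setting of GLUT10 did not differ from other genes by camera. Of 37 TGF-beta and BMP pathway components 2 were called, both on the opposite side, smad5 (-0.23 ± 0.14) and bmp7a (-0.19 ± 0.07), and none when adjusted over the list alone (adjusted p = 0.84). Transcriptional targets of the pathway went both ways, with 5 of 31 called on each side (6 and 8 adjusted over the list alone; adjusted p = 0.46). The genes id4 (0.80 ± 0.08) and id2a (0.51 ± 0.10), encoding inhibitors of helix-loop-helix factors, were on the slc2a10 side. The genes snai1a (-0.93 ± 0.17) and fn1b, a fibronectin gene (-0.61 ± 0.12, 2 of 3 probes on this side), were opposite. Of 26 collagen genes 2 were called on the slc2a10 side and 3 opposite, the same counts as adjusted over the list alone (adjusted p = 0.43). Col14a1a (-0.47 ± 0.12), col1a1a (-0.20 ± 0.09) and col28a2a (-0.20 ± 0.08) were opposite to col10a1a. Of 33 elastic fibre and crosslinking genes 4 were called on the slc2a10 side and 2 opposite (4 and 3 adjusted over the list alone; adjusted p = 0.87). The biglycan paralogs differed in sign, bgna at 0.41 ± 0.05 and bgnb at -0.52 ± 0.09. Lum, encoding lumican, had 0.33 ± 0.06, and the microfibril gene mfap2 had 0.24 ± 0.04.

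Among vascular and muscle markers, 5 of 34 endothelial genes were called, all on the opposite side (3 adjusted over the list alone; adjusted p = 0.15). Without replicate 1 this list passed (median -0.07, adjusted p = 0.041), and without replicate 3 its median was -0.01 (adjusted p = 0.37). These included the growth factor gene vegfaa (-0.35 ± 0.06), stab2 (-0.22 ± 0.01, 1 of 2 probes on this side), ephb4a (-0.22 ± 0.07) and sox18 (-0.31 ± 0.25), which was -0.17 without replicate 1 (adjusted p = 0.085). Of 23 smooth muscle and pericyte markers 1 was called on the slc2a10 side, tpm1 (0.42 ± 0.11), and 3 opposite, acta2 (-0.81 ± 0.53), myl9a (-0.34 ± 0.23) and tagln (-0.44 ± 0.39), the same counts as adjusted over the list alone (adjusted p = 0.79). On replicates 1, 2 and 3 acta2 had -0.28, -0.80 and -1.34, and tagln -0.05, -0.44 and -0.82. Both lost their call with robust eBayes, and tagln was -0.25 without replicate 3 (adjusted p = 0.11). Of 29 cardiac markers 3 were called on the slc2a10 side and 5 opposite, the same counts as adjusted over the list alone (adjusted p = 0.85). The contractile genes myh7 (0.57 ± 0.08) and myl4 (0.57 ± 0.09) and the natriuretic peptide gene nppa (0.44 ± 0.06) were opposite in sign to the transcription factor gene gata5 (-0.65 ± 0.05). Of 18 notochord markers 2 were called, entpd5a (0.25 ± 0.09) and matn4 (0.26 ± 0.18), both on the slc2a10 side (1 adjusted over the list alone; adjusted p = 0.45).

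Genes of liver, skeleton, skin and blood held large differences without a shift of the whole list by camera. Of 52 liver, yolk and gut genes 14 were called on the slc2a10 side and 7 opposite (16 and 10 adjusted over the list alone; adjusted p = 0.24). The transferrin gene tfa (1.09 ± 0.10, 6 probes) and the trypsin gene prss1 (1.05 ± 0.14) lay with fabp10a, and the apolipoprotein E gene apoeb opposite (-0.90 ± 0.10). Of 31 cartilage and bone genes 8 were called on the slc2a10 side and 1 opposite, the same counts as adjusted over the list alone (adjusted p = 0.24, and adjusted p = 0.024 by fry against no change). Besides col10a1a and matn1 they included chad (0.43 ± 0.03) and sparc (0.42 ± 0.06). Of 41 epidermis and ionocyte genes 7 were called on the slc2a10 side and 11 opposite (8 and 12 adjusted over the list alone; adjusted p = 0.24). The keratin genes krt91 (1.08 ± 0.08) and krt92 (0.62 ± 0.05) were on the slc2a10 side, and zgc:111983 was opposite (-0.78 ± 0.06). Over all 20 measured keratin genes, a family formed after the values were seen, 7 were called on the slc2a10 side and 3 opposite (adjusted p = 0.060, and adjusted p = 0.59 with an estimated correlation). The keratin median was 0.05. It was 0.095 without replicate 2 and 0.10 without replicate 3, where camera passed (adjusted p = 0.0097 and 0.019). Without replicate 1 it was 0.03 (camera adjusted p = 0.11). Of 23 erythroid genes 7 were called on the slc2a10 side and 2 opposite (9 and 3 adjusted over the list alone; adjusted p = 0.45). The embryonic beta globin gene hbbe2 (0.87 ± 0.20) and the carbonic anhydrase gene cahz (0.67 ± 0.13) were opposite in sign to hbbe3.

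Stress-related lists went both ways and did not pass by camera. Of 34 oxidative stress genes 8 were called on the slc2a10 side and 4 opposite, the same counts as adjusted over the list alone (adjusted p = 0.45). The antioxidant genes gpx4a (0.78 ± 0.10), sod1 (0.47 ± 0.07), sod2 (0.58 ± 0.16) and gstp1.2 (0.39 ± 0.13) were all on the slc2a10 side. Of 28 hypoxia genes 3 were called on the slc2a10 side and 6 opposite (4 and 6 adjusted over the list alone; adjusted p = 0.46). The paralogs ndrg1b (1.04 ± 0.22) and ndrg1a (-0.48 ± 0.17) were opposite in sign, and igfbp1a had -0.60 ± 0.03. Of 49 heat shock and unfolded protein response genes 5 were called on the slc2a10 side and 8 opposite (6 and 10 adjusted over the list alone; adjusted p = 0.79). The chaperone genes hsp90ab1 (-0.46 ± 0.08) and hspb1 (-0.49 ± 0.23) were opposite to ddit3 (0.33 ± 0.06) and dnajb9a (0.33 ± 0.09). Of 25 p53 targets 3 were called on the slc2a10 side and 4 opposite (4 and 7 adjusted over the list alone; adjusted p = 0.28). The opposite 4 were pcna (-0.56 ± 0.09), which is also in the replication list, tnfrsf1a (-0.36 ± 0.15), btg2 (-0.32 ± 0.11) and plk3 (-0.25 ± 0.03).

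The median, mean and tests of a list differed in sign for 5 lists. The collagen genes had a median of -0.02 and a mean of 0.04, with camera on the opposite side and fry on the slc2a10 side. Hypoxia genes (median 0.001, mean -0.0004) and heat shock genes (median 0.003, mean -0.009) had camera on the opposite side. For elastic fibre genes (median -0.002) and smooth muscle markers (median -0.006), fry and camera had different signs. These medians lay near 0 and moved with single arrays. Without replicate 1 they were -0.07 for collagens, -0.06 for heat shock genes and -0.04 for hypoxia genes. Without replicate 3 they were -0.004 for collagens, 0.07 for heat shock genes, 0.03 for elastic fibre genes and -0.04 for smooth muscle markers.

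Of the 114 named genes that were called, 16 lost their call without replicate 2, the only array of its dye order. Of the same 16 genes, 7 lost it without replicate 3 and 4 without replicate 1. With a dye term 11 of these 16 also lost it, namely smad5, bmp7a, col28a2a, col1a1a, mfap2, entpd5a, matn4, stab2, ephb4a, sox18 and socs3a. The other 5 were myl9a, tagln, b2m, plk3 and ND5. Medians of 3 called lists moved by over 1.5 times without 1 array while the list stayed called. Retina and lens genes went from 0.09 to 0.15 and neural crest and pigment cell genes from 0.08 to 0.13 without replicate 3, and leukocyte markers from -0.07 to -0.12 without replicate 2.

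The 3 arrays did not scatter alike around their mean. After the turn, the correlation across genes was 0.74 between replicates 1 and 2, 0.77 between replicates 2 and 3, and 0.57 between replicates 1 and 3, which share a dye order. Genes are not independent replicates. Replicates 1 and 3 lay over 0.75 log2 apart on 92 genes, and replicate 2 lay between them on all 92. At over 0.5 log2 the share was 361 of 379 genes (95.3%). The same share was 29.2% of 96 genes with replicate 1 as the middle array and 36.8% of 114 genes with replicate 3. An example is cyp1a, the aryl hydrocarbon receptor target gene, chosen after its values were seen. Its 3 probes averaged -1.31, 0.72 and 2.27 on replicates 1, 2 and 3, and it was not called.

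**Figure D3:**
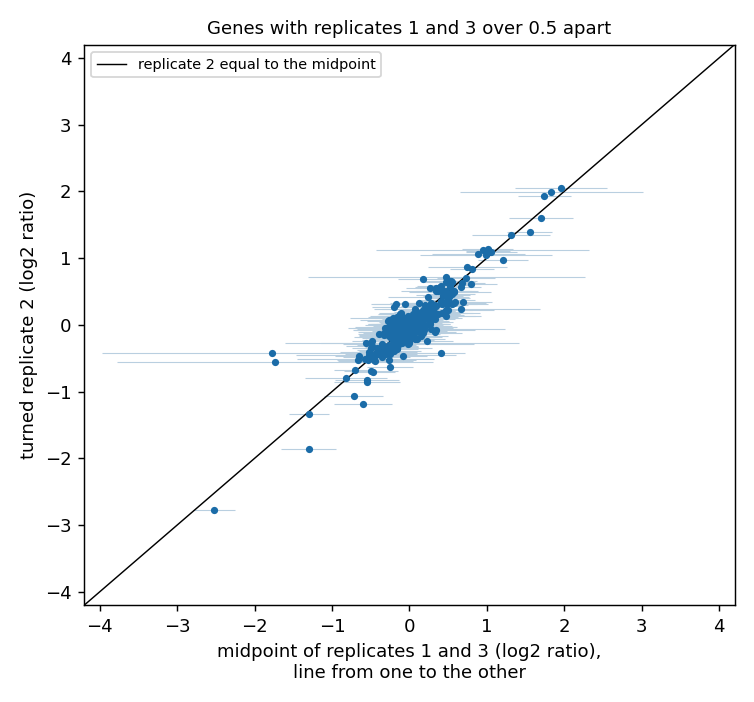
Turned log2 ratio of replicate 2 (y axis) against the midpoint of replicates 1 and 3 (x axis) for the 379 genes on which replicates 1 and 3 lay over 0.5 log2 apart, with 1 point per gene and a pale line from one replicate to the other. The points follow the diagonal, where replicate 2 equals the midpoint.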

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

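Counts of genes on both sides together, on the slc2a10 side, on the opposite side, and of probes were 2996, 1728, 1268 and 5090. They stayed within 1.5 times of this with a dye term (2221 genes), centring (2938), scaling (3050), quantile normalization (3038), robust eBayes (2995) and gene medians (2991), and turning all signs exchanged the sides. They moved to 5211, 2722, 2489 and 7827 with array weights, to 297, 202, 95 and 643 with a 1.5-fold minimum, to 2, 1, 1 and 3 with an ordinary t statistic (3262 genes at an unadjusted p under 0.05), and to 0, 0, 0 and 0 in limma with the opposite turn of replicate 2 (28 genes at an unadjusted p under 0.05). That turn left slc2a10 at 0.18 (adjusted p = 0.9999), 2 called lists and ND5 reversed at -0.027; it sets replicate 2 against the other arrays by construction. Leaving out single replicates gave 1556 to 3211 genes, 981 to 1642 on the slc2a10 side, 575 to 1569 on the opposite side and 2897 to 6593 probes, each lowest without replicate 2; of the 1556 genes 1529 were among the 2996 with the same side. The value of slc2a10 was 0.44 to 0.48 in these fits, and 9 or 10 lists were called, the list gained without replicate 1 being the endothelial one (adjusted p = 0.041). Lists called numbered 9 with a dye term and with quantile normalization, 0 with an estimated correlation, 4 by directional fry and 27 by mixed fry, and neither fry test compares a list with other genes. Of 123 named genes 114 were called. All 114 lost their call with the ordinary t statistic and with the opposite turn of replicate 2 (113 in the same direction, ND5 reversed). In the same direction 54 lost it with the 1.5-fold minimum, 16, 7 and 4 without replicates 2, 3 and 1, 11 with the dye term and 3 with robust eBayes. The causes were not tested beyond what each setting does. A filter on dim probes was not run, since the values carry no signal level or flag, and signal over background is unknown.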

Other observations

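The gene families and the tests on replicate 2 and on dye bias were chosen after the values were seen. The list of earlier embryonic genes and its test, and the count of sign patterns, were fixed before their values were looked up. A test of spot noise on the gene pcmt was dropped after its result was seen, because it assumed probes that agree and the 4 probes of pcmt do not. A test of the direction of the ratios by the value of slc2a10 was dropped after its result was seen, because an MO at a splice site allows either sign. Families were formed from gene symbols and 16 were tested, of which 8 passed by camera. None passed with an estimated correlation, where the adjusted p of these 8 was 0.40 to 0.59. That form of camera has 2 degrees of freedom and also another correlation, and the failure alone does not tell these apart. Camera's unadjusted p rose from 0.00015 to 0.30 for crystallins and from 2.8e-06 to 0.035 for subunits of the V-type proton pump. Correlation among members is therefore not excluded as a source of calls such as that of the crystallins. Symbols of other proteins (krtcap2, tcp11l1, tcp11l2 and the tubgcp genes) were taken out of the keratins, chaperonin subunits and tubulins after a first run, and the same 8 passed before and after. The list of families is not independent of the genes described above.

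Of 68 mitochondrial ribosomal protein genes 31 were called on the slc2a10 side and 0 opposite (median 0.18, camera adjusted p = 5.4e-10, and adjusted p = 0.40 with an estimated correlation). Mrpl48 (0.44 ± 0.11) and mrps34 (0.39 ± 0.02) were among them. The 72 cytosolic ribosomal protein genes had 3 and 2 called (median -0.02, camera adjusted p = 0.22). Without replicate 3 that family passed (median -0.06, camera adjusted p = 0.029), and without replicate 2 its median was 0.003. Of 6 creatine kinase genes 4 were called on the slc2a10 side, and 1 opposite (camera adjusted p = 0.011). The mitochondrial ckmt2a (1.01 ± 0.18) and ckmt1 (-0.28 ± 0.12) differed in sign, and the cytosolic ckbb (0.74 ± 0.10), ckmb (0.29 ± 0.10) and ckma (0.27 ± 0.12) lay on the slc2a10 side. Of 45 proteasome subunit genes 11 were called on the slc2a10 side and 0 opposite, at small sizes such as psmc6 (0.36 ± 0.06; camera adjusted p = 0.0025).

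Of 23 subunits of the V-type proton pump, which acidifies lysosomes and synaptic vesicles, 13 were called on the slc2a10 side and 1 opposite (camera adjusted p = 2.2e-05). Atp6v0cb stood at 0.67 ± 0.03, and the 1 opposite was atp6v0e1 (-0.55 ± 0.12). Of 14 cathepsin genes, which encode mostly lysosomal proteases, 6 were called on the opposite side and 2 on the slc2a10 side (camera adjusted p = 0.0026). After ctss2.1 and ctsh these were ctsla (-0.75 ± 0.08), ctsd (-0.44 ± 0.19), ctsc (-0.37 ± 0.08) and ctsba (-0.32 ± 0.02), while ctsll (0.47 ± 0.28) and ctsz (0.23 ± 0.12) lay on the slc2a10 side. Leukocytes are rich in several cathepsins, and of 23 leukocyte markers 8 were called on the opposite side, 0 on the slc2a10 side and 15 not (adjusted p = 0.50 with an estimated correlation). Of 39 synaptotagmin and SNARE genes 12 were called on the slc2a10 side and 1 opposite, led by syt5b (1.09 ± 0.15; camera adjusted p = 0.011). Of 37 crystallin genes 14 were called on the slc2a10 side and 2 opposite, with crygm2d11 at 1.05 ± 0.34 (camera adjusted p = 0.0008). Of 38 genes of hnRNP and SR splicing factors 10 were called on the opposite side and 1 on the slc2a10 side (camera adjusted p = 0.025), including srsf6b (-0.64 ± 0.10) and hnrnpa1b (-0.56 ± 0.11). All 8 families were also called without each of the 3 arrays in turn, when 11, 11 and 10 of the 16 were called without replicates 1, 2 and 3. Among these 8 families, medians moved by over 1.5 times for crystallins (0.12, and 0.07 without replicate 1 and 0.18 without replicate 3) and for synaptotagmins and SNAREs (0.04, and 0.08 without replicate 2).

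Replication genes stood opposite to oxidative phosphorylation genes. The replication list median was -0.4123 on turned replicate 2, but replicate 2 was turned because it ran against the other arrays, so its sign decides nothing about a gene-specific dye bias, which stays open. Replicates 1 and 3, which share a dye order, correlated less across genes (0.57) than either did with replicate 2 (0.74 and 0.77). Dye bias alone on equally noisy arrays would not give this. Limma weighted replicate 2 as the quieter array, however, so the correlations do not settle dye bias either. A difference in developmental stage could put early genes with the replication genes. Of 44 genes of earlier stages 6 were called on that side and 3 on the slc2a10 side, and of 43 genes of later larval stages 1 and 8. For the early list the unadjusted value of limma's camera was 0.05931, just above the threshold set for it, and the adjusted p of both lists was 0.10 (0.21 with an estimated correlation). Fry, which compares a list with no other genes, gave an adjusted p of 0.0155 for the early list (median -0.03) and 0.038 for the later list (median 0.04). These results leave stage open, and the sorting of knockdown embryos, the MO dose and an effect of slc2a10 on growth or metabolism cannot be told apart in this design.

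Replicate 2 lay between replicates 1 and 3 on 95.3% of the genes on which those differed by over 0.5 log2. The share was 29.2% and 36.8% for the other arrays. If genes varied independently, 3 independent and equally variable replicates would give like shares. Genes that vary together would share 1 middle array, however, so the shares do not decide whether the replicates were independent. A full gene-wise dye correction would put replicate 2 at the midpoint exactly, and its median distance from it was 0.07223. RNA pooled from several replicates is a candidate source, with a median position between the others (0 at replicate 1, 1 at replicate 3) of 0.505 over the genes on which those differed by over 0.75 log2 and 0.542 at over 0.5 log2, but an array with little deviation of its own would lie there too. Limma's array weights were 2.81 for replicate 2 and 0.51 and 0.70 for the others, and the 45 control spots showed a like ratio of variances (0.31, bootstrap 95% interval 0.20 to 0.48, against 0.29 over genes and 0.75 for equally variable independent arrays). If control spots do not bind embryo transcripts, pooled RNA alone would leave their ratio near 0.75 on equally noisy arrays. On that condition they would argue against pooled RNA as the only source of the pattern. The spots were set apart by probe name and what they bind was not checked, so they do not decide this. Pooled RNA, joint processing, a quieter array 2 and genes that vary together stay open. If the arrays were not independent, limma's p-values are too small.

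Of the 4 sign patterns of the 3 arrays, 1 gave as many genes as the real one, which is the real one itself with 2996, and the highest of the others gave 0. The real pattern follows the turn, which was itself taken from the correlations. With 4 patterns no share under 0.05 can be reached. Replicate 1 carried extreme values of 2 single-probe genes: aggf1 had -3.77, -0.56 and 0.31 on replicates 1, 2 and 3, and si:ch211-241b2.4 had -3.96, -0.42 and 0.41.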
